A study of Mus musculus with 8 samples.

How the data were processed

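DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), which reads CpG-rich restriction fragments after bisulfite conversion, in 8 libraries of mouse I1DN leukaemic progenitors (cKit positive, Cd11b negative; I1DN as in the labels). The cells came from transplanted mice that received Vehicle, AG120 (ivosidenib, an inhibitor of mutant IDH1), AZA (azacitidine, a DNA methyltransferase inhibitor) or both drugs, here called the combination. Per the labels each group had 2 libraries and treatment lasted 5 days. Libraries were made with a commercial RRBS kit that includes methylated and unmethylated spike-in DNA, and the spike-in values were not used here.

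The deposited table holds, per the file headers, raw counts of reads that called a cytosine methylated and unmethylated at each CpG cytosine of each library, with the strands listed separately and no normalization. The submitters' processing notes list bcl2fastq 2.17.1.14, Trim Galore 0.4.4, Bismark 0.22.3, SAMtools 1.4.1, R 4.0.2, edgeR 3.32 and the mm10 build, without roles or order. Deduplication, alignment filters and the conversion rate are not given in the sources used here. All count columns matched a library's label, and 0 columns of per-sample values were left unused. The table held 4006353 CpG cytosine positions, of which 4003423 lay on the 19 autosomes and X. Total CpG calls per library ranged from 90373925 to 130796962, and 34585 positions on these chromosomes had at least 10 reads in all 8 libraries. PCR reads are not independent molecules, so intervals and upper limits for a count of 0 (3 counts of the total) cover counting error only.

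Mean methylation of a library was the unweighted mean level of the positions with at least 10 reads in every library. Each drug was tested as a factor, 4 libraries with it against 4 without, by a two-sided exact permutation test over 70 assignments, with a 95% interval from the same permutations. The same test was applied to 11 classes of positions, adjusted by Benjamini and Hochberg over the classes of a factor. For tests of regions, counts were summed over tiles of 1000 bp and over gene-end windows, with at least 3 positions and at least 20 reads in every library. The gene table used here (GRCm38.p6 coordinates, which are those of mm10) gives no strand. A gene-end window therefore ran from 1000 bp outside to 500 bp inside the end of the gene that held more covered positions, and the lower coordinate was taken at a tie. Such a window is not known to be a promoter. Among 13043 genes with a window, 79.9% of windows had a mean level under 20%. At the other end, which passed the same filter in only 1072 genes, 43.8% of windows did. Genome sequence, CpG island, exon and intron annotation were not used here.

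Methylated and unmethylated counts of each region were fitted with edgeR 4.0.16 under R 4.3.3, with a term per library and a methylation term per group, and tested with the robust quasi-likelihood F-test, two-sided, at a false discovery rate of 0.05. All 8 libraries of the 4 groups shared 1 fit. Of the contrasts, 5 compared pairs of groups, and the others were the interaction of the drugs and the average effect of each drug. The lists of genes, 14 in number, held stem and progenitor, myeloid, lymphoid, erythroid and megakaryocytic, stromal and endothelial, germline, imprinted, developmental transcription factor, tumour suppressor, cell cycle, methylation machinery and IDH, interferon, MAPK and housekeeping genes. Ndn and Cdkn1c stood in both the stem and the imprinted list, and the lymphoid, erythroid and stromal lists held markers of other cell types. Of 385 list entries 384 matched the gene table. The 13 lists with at least 3 measured members were tested with camera (preset correlation 0.01 and an estimated correlation) and fry in limma 3.58.1 on log2 ratios of methylated to unmethylated counts with a pseudocount of 2. In fry, the directional p asks whether members move on balance one way and the mixed p whether they move in either direction, and neither compares a list with other genes.

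Named genes were chosen by a rule. In each pairwise comparison it took, among windows past the threshold with groups that did not overlap, the 8 with the largest loss and the 8 with the largest gain, or, with fewer than 3 past the threshold, the 3 with the smallest p, named as not past it. It also took the 2 members of each list with the smallest p in the combination against Vehicle, and Idh1, Dnmt3a, Tet2, Nras and Cdkn2b where measured. Genes chosen by the rule that shared an interval or the same counts were named together. Some windows also overlap the window of another gene. These were Bmi1 (Commd3), Mbd4 (Ift122), Spry4 (Arhgap26), Plagl1 (Hymai), Gata6 (Gata6os), Sp7 (Gm36246) and Zc3h18 (Gm39270). Tiles were to be named only past the threshold, and 0 passed it. The groups, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined; the gene-end definition and the classes by gene position and by position density followed from the gene table and were set afterwards.

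Alternatives were minimum reads of 10, 40 or 1 per region and of 5 or 20 per position, read-weighted means, autosomes alone, 2000 bp tiles, windows from 2000 bp outside to 1000 bp inside, equal library sizes, a minimum difference of 10 points, a replicate block, the edgeR likelihood ratio test, limma with and without centring, DESeq2 1.42.0 on windows, and leaving out each library. The whole gene and the gene end with fewer covered positions were added after the data were seen. Calls were also counted over all 35 splits of the libraries into 4 and 4. Detection was tested on simulated data built from these libraries, with 70 regions lowered by 20, 40 or 80 points. The lowered regions were drawn only from highly methylated ones, all with a mean level over 80%. Y was left out of the tiles and windows, because few of its positions were covered. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.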

Results

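Methylation of CpG cytosines was read in 8 RRBS libraries of mouse I1DN leukaemic progenitors, 2 each from mice given Vehicle, AG120, AZA or the combination for 5 days. The series asks what combined inhibition of mutant IDH1 and treatment with a DNA methyltransferase inhibitor does to DNA methylation. The Vehicle libraries held 119441709 and 130796962 CpG calls, the AG120 libraries 98639402 and 110137175, the AZA libraries 130120463 and 128484739, and the combination libraries 97741404 and 90373925. Of 4006353 covered positions, 138110 (3.45%) had a read in all 8 libraries. In the text, a value after ± is the SD over the libraries of a group (n = 2), or over the 4 libraries with or the 4 without a drug where these are compared, and every window or tile compared had at least 20 reads in every library.

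The libraries with AG120 stood apart from those without it in coverage. Each of the 4 held fewer calls than any of the other 4, and they covered a mean of 1524150 positions against 1905860. Of all their calls, 47.5% ± 4.10 were methylated, against 35.7% ± 2.93 in the libraries without AG120. The exact permutation p was 0.0286 for each of these 3 measures, two-sided, the smallest that 4 libraries against 4 can give. Median reads per gene-end window were 3370 and 3900 in the Vehicle libraries, 3198 and 3339 with AZA, 2229 and 2162 with AG120, and 1688 and 1672 with the combination. In the same order, 11.2 and 9.64%, 16.1 and 13.8%, 23.3 and 21.7%, and 31.2 and 29.2% of 13003 windows had no methylated read.

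Libraries of a group resembled each other about as much as libraries of different groups. At single positions, Pearson's r lay between 0.757 and 0.795 (mean 0.769) in the 4 pairs within a group and between 0.743 and 0.795 (mean 0.768) in the 24 pairs between groups. Between 9.28 and 13% of positions differed by more than 50 points within a group, and between 10.1 and 13.5% between groups. Over tiles, the mean r was 0.881 within and 0.879 between groups. Positions and tiles are not independent replicates, and no pair of libraries was a duplicate. At 2636 positions with a mean level between 30 and 70%, 22.5% (Vehicle replicate 2) to 37.6% (combination replicate 1) stood at exactly 0 or 100% in a library, where the median depth was 224 to 287 reads.

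**Figure D1:**
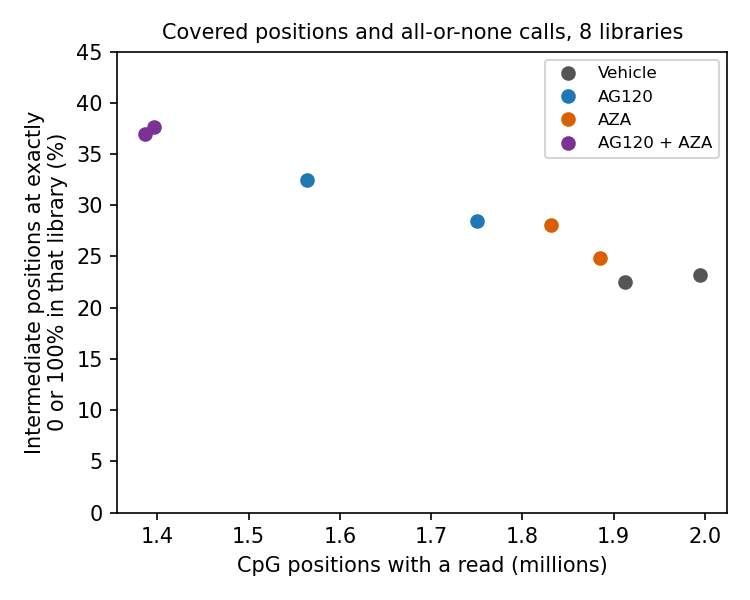
Share of intermediate CpG positions (mean level between 30 and 70% over the libraries) that stood at exactly 0 or 100% in a library, in percent, against the number of CpG positions with a read in that library; each dot is a library, coloured by group. The combination libraries lie highest, at 37.0 and 37.6%, and the Vehicle libraries lowest, at 22.5 and 23.1%.

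Mean CpG methylation was nearly level across the groups when each of 34585 shared positions counted once. It was 39.5% ± 0.568 in Vehicle, 39.8% ± 1.07 in AG120, 38.5% ± 0.944 in AZA and 39.5% ± 0.115 in the combination. The 4 libraries with AZA, an inhibitor of maintenance and de novo methyltransferases, differed from the 4 without it by −0.604 points (95% interval −2.67 to 0.574; exact permutation p = 0.371, two-sided). The 4 libraries with AG120 differed from the 4 without it by 0.651 points (−0.849 to 2.67; exact permutation p = 0.343). With each library left out in turn, the AZA difference ran from −0.829 to −0.231 points, the latter without AZA replicate 2, and its interval reached at most −3.59. The AG120 difference ran from 0.327 points, also without AZA replicate 2, to 1.04, and its interval reached at most −1.63 and 3.59. When every read of the same positions counted, the group means were 40.9% ± 0.384, 50.6% ± 5.33, 44.5% ± 1.41 and 50.5% ± 0.334 in the same order. The libraries with AG120 then stood 7.83 points higher (interval 1.4 to 13.7, exact permutation p = 0.0286), and the AZA difference turned to 1.74 points (exact permutation p = 0.657). Counted once over each library's own positions with at least 10 reads, which differ between libraries, the level was 43.8% ± 3.57 with AG120. It was 35.6% ± 1.37 without AG120, a difference of 8.12 points (exact permutation p = 0.0286). Levels were also close over 44516 tiles with at least 20 reads in every library, whose covered positions may differ between libraries. The AG120 difference there was 0.788 points (−1.27 to 3.29; exact permutation p = 0.314), and the AZA difference −0.751 points (exact permutation p = 0.343). The nearly level means thus hold for the shared positions and for these tiles, and not for each library's own positions.

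**Figure D2:**
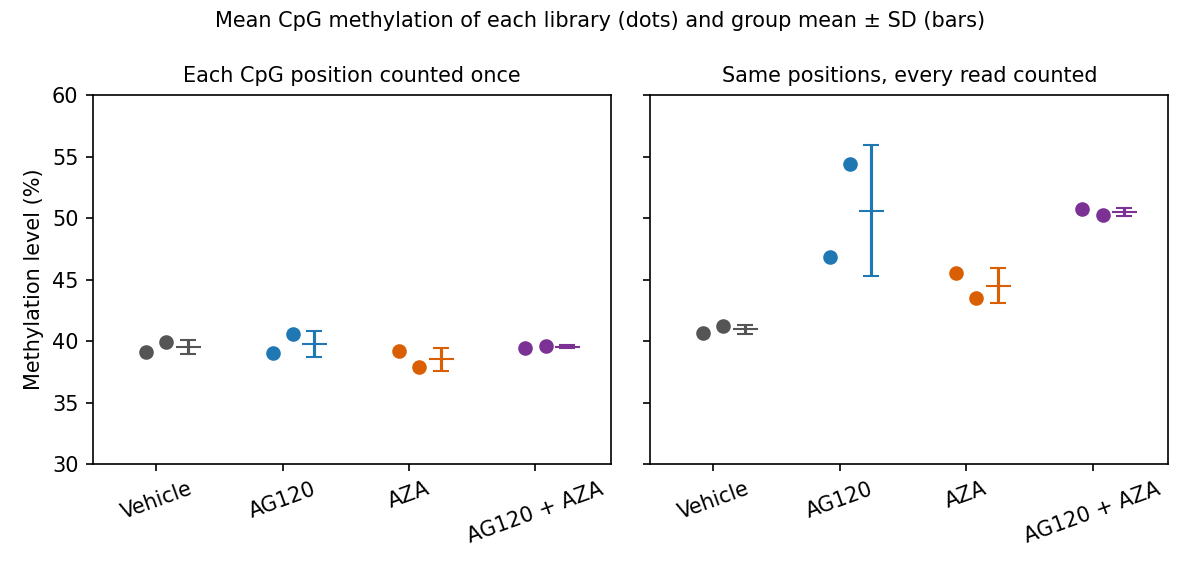
Mean methylation level of 34585 CpG positions with at least 10 reads in all 8 libraries, in percent (axis from 30 to 60), with each position counted once on the left and every read counted on the right; dots are libraries and bars the group mean ± SD (n = 2). Group means lie between 38.5 and 39.8% on the left, and reach 50.6% with AG120 and 50.5% with the combination on the right, against 40.9% in Vehicle.

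Methylation was lower near gene ends than inside genes, and higher between genes than inside them. Positions near a gene end had a level of 11.7% ± 0.0115 in Vehicle, 12% ± 0.727 in AG120, 11.1% ± 0.739 in AZA and 12.1% ± 0.190 in the combination. Inside genes the levels were 47.0% ± 0.810, 47.1% ± 0.951, 45.7% ± 1.07 and 46.6% ± 0.396, and between genes 69.2% ± 1.04, 69.9% ± 1.80, 68.2% ± 1.04 and 69.5% ± 0.0979. On X they were 69.2% ± 0.287, 71.0% ± 5.16, 66.3% ± 1.72 and 70.2% ± 0.416. Positions with a mean level over 80% had 94.8% ± 0.630, 94.8% ± 0.643, 93.0% ± 1.21 and 94.4% ± 0.193. The difference with AZA in that class was −1.07 points (exact permutation p = 0.114, adjusted p = 0.503). Positions in stretches of 60 or more covered positions per kb were 1.52 points higher with AG120 (0.303 to 2.59; exact permutation p = 0.0286, adjusted p = 0.314). None of the 22 tests, over 11 classes and both drugs, passed an adjusted p of 0.05, but a single class at the smallest exact p could reach no less than 0.314. The classes also took different shares of the reads: with AG120, positions over 80% took 36.7% of the calls against 30.1% without it, and dense stretches 37.6% against 45.1% (exact permutation p = 0.0286 for both).

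The comparison of AG120 with Vehicle asked what inhibition of mutant IDH1 does alone. Gene-end windows with the smallest p were near 0 with AG120 and low but methylated in Vehicle. The window of Josd1, a deubiquitinase gene (chromosome 15, 79687372 to 79688872), had 1.64% ± 0.565 in Vehicle and 0% in AG120, where its reads allow up to 0.0269%. Gm38737 (chromosome 5, 143731455 to 143732955) had 2.09% ± 0.342 and 0.0172% ± 0.0244. Cc2d1b and Gm12743, whose windows on chromosome 4 (108618940 to 108620440 and 108619444 to 108620944) hold the same reads, had 2.64% ± 1.4 and 0%, which allows up to 0.0175%. The edgeR p was 0.00348 for Josd1, 0.00444 for Gm38737 and 0.00468 for Cc2d1b and Gm12743, each with an adjusted p of 1. Josd1 and Cc2d1b were at 0.0232% ± 0.00333 and 0.0353% ± 0.0334 with AZA, and Gm38737 was at 1.59% ± 0.824. Windows without any methylated read were more frequent in every AG120 library than in Vehicle, as given above.

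Stem and progenitor genes were lower with AG120 than in Vehicle in 10 of 14 measured windows, with a median difference of −1.16 points. Their mean level was 8.20% ± 1.97 against 11% ± 2.69, and the camera p of 0.0251 gave an adjusted p of 0.326 (adjusted p = 0.946 with an estimated correlation). Much of the difference lay in Vehicle replicate 1 (12.9%), while Vehicle replicate 2 (9.09%) was below AG120 replicate 2 (9.59%). The MAPK genes were lower in 19 of 30 windows, with 2.82% ± 0.247 against 5.12% ± 0.970 (camera adjusted p = 0.898). Myeloid genes were higher in 6 of 10 windows, with 19.5% ± 10.3 against 8.91% ± 4.21. Their median (1.35 points) and mean (10.6 points) were positive, while camera gave the direction down (adjusted p = 0.898). Imprinted genes were lower in 8 of 12 windows, at 43.4% ± 1.05 against 45.2% ± 2.77, where camera gave the direction up (adjusted p = 0.898). No list passed camera in this comparison, with either correlation, and no member passed when adjusted over the list alone.

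Over the genome, the edgeR quasi-likelihood test called 0 of 44190 tiles and 0 of 13003 windows for AG120 against Vehicle. At an unadjusted p under 0.05 it had 1257 tiles and 423 windows. Limma called 0 of both (2060 tiles and 634 windows under 0.05), the likelihood ratio test 8 tiles and 0 windows (4180 and 1329 under 0.05), and DESeq2 197 windows, 40 higher and 157 lower. Groups did not overlap in 30.5% of tiles, where chance gives 33.3%. Of these, 5841 tiles were higher with AG120 and 7635 lower, and by at least 10 points 3410 were higher and 3090 lower. The mean tile difference was 0.345 points. It turned to −0.197 without Vehicle replicate 1 and to −0.775 without AG120 replicate 2, and rose to 1.48 without AG120 replicate 1.

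With AZA alone, which asks for the effect of the methyltransferase inhibitor without AG120, the windows with the smallest p were again near 0 where Vehicle was low. Aven, an inhibitor of apoptosis (chromosome 2, 112491883 to 112493383), had 1.69% ± 0.445 in Vehicle and 0.00612% ± 0.00866 in AZA. Socs7, a member of the suppressor of cytokine signalling family (chromosome 11, 97361292 to 97362792), had 1.53% ± 0.748 and 0%, which allows up to 0.0308%. Gm35986 (chromosome 3, 129531888 to 129533388), whose window overlaps that of the fatty acid elongase gene Elovl6, had 7.06% ± 0.580 in Vehicle and 0.00973% ± 0.0138 in AZA. Gm35986 was at 0.00990% ± 0.0140 with AG120 and at 0% with the combination, which allows up to 0.0829%. The edgeR p was 0.00441 for Aven, 0.00528 for Socs7 and 0.00628 for Gm35986, each with an adjusted p of 1.

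Housekeeping genes were higher with AZA than in Vehicle in 10 of 13 windows, with a mean level of 8.03% ± 2.24 against 5.11% ± 0.222. The camera p was 0.0464 and the adjusted p 0.603 (adjusted p = 0.917 with an estimated correlation). Stromal and endothelial genes, markers of another cell type, were lower in 4 of 4 windows, with 33.3% ± 1.92 against 47.9% ± 4.72 and a median difference of −11.4 points (camera adjusted p = 0.878). Imprinted genes were lower in 8 of 12 windows, with 42.0% ± 2.03 against 45.2% ± 2.77 and a median of −8.34 points, where camera gave the direction up (adjusted p = 0.915). Germline genes, which are methylated at their gene ends outside the germ line, stood at 94.5% ± 3.36 against 93.1% ± 0.300. Their median (−0.412 points) and mean (1.39 points) differed in sign. No list passed camera for AZA against Vehicle, with either correlation, and no member passed when adjusted over the list alone.

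For AZA against Vehicle, the edgeR quasi-likelihood test called 0 of 44190 tiles and 0 of 13003 windows, with 1089 tiles and 297 windows at an unadjusted p under 0.05. Limma called 0 of both (2117 tiles and 571 windows under 0.05), the likelihood ratio test 8 tiles and 2 windows, and DESeq2 92 windows, 23 higher and 69 lower. Groups did not overlap in 30.9% of tiles (33.3% by chance without ties). Of these, 5443 were higher and 8202 lower, of which 2735 and 3946 by at least 10 points. The mean tile difference was −1.21 points, between −0.567 without AZA replicate 2 and −1.89 without AZA replicate 1. Data were simulated with a spread between libraries modelled on that within groups. Each region's own spread was averaged with that of regions of like level. On these data the quasi-likelihood test recovered 0% of regions lowered by 20, 40 or 80 points. The lowered regions all had a mean level over 80%. Detection in regions under 20%, where 79.9% of windows lay, was therefore not simulated. Limma recovered 0% of tiles and, at 80 points, 11.4% of windows. At 80 points the likelihood ratio test recovered 37.1% of tiles and 62.9% of windows, with 103 and 123 false calls. DESeq2 recovered 91.4% of windows with 298 false calls, and each of these false-call counts was the most among the 5 comparisons. They outnumber all calls of the same tests on the real data, which were 8 tiles and 2 windows, and 92 windows. The simulated spread may thus be wider than that of these libraries, so its recovery rates may not carry over. Without spread between libraries the quasi-likelihood test recovered 100% of lowered windows with 4 false calls, so a count of 0 here does not show that no region differed.

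The combination against Vehicle addressed the question in the study's design. Ppargc1a, a coactivator of mitochondrial biogenesis (chromosome 5, 52115353 to 52116853), had 4.01% ± 1.60 in Vehicle and 0% in the combination, which allows up to 0.0196%. 1110059E24Rik and the depalmitoylase gene Abhd17b, whose windows on chromosome 19 overlap (21652291 to 21653791 and 21652267 to 21653767), had 1.94% ± 0.469 and 1.98% ± 0.526 in Vehicle, and both had 0.00471% ± 0.00667 in the combination. Their edgeR p was 0.000683, 0.000745 and 0.000797, each with an adjusted p of 0.938. Ppargc1a was at 0.0825% ± 0.0502 with AG120 and at 6.01% ± 3.22 with AZA, while 1110059E24Rik was at 2.72% ± 1.58 and 0.422% ± 0.213.

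Stem and progenitor genes were lower in the combination than in Vehicle in 11 of 14 windows, with 9.05% ± 0.506 against 11% ± 2.69 and a median of −1.10 points. The difference in means lay almost wholly in Vehicle replicate 1 (12.9%), as Vehicle replicate 2 stood at 9.09%. Bmi1, a Polycomb gene needed for stem cell self-renewal, had 1.13% ± 0.774 in Vehicle and 0.00432% ± 0.00611 in the combination (edgeR adjusted p = 0.938). Cd34, a surface marker of progenitors, had 4.19% ± 4.40 and 0%, which allows up to 0.126% (edgeR adjusted p = 0.938). The camera p of this list was 0.0249 and its adjusted p 0.323 (adjusted p = 0.697 with an estimated correlation). Fry's mixed test gave an adjusted p of 0.00699, which passed in 9 of 16 alternatives (range 0.00299 to 0.598). Methylation machinery genes were lower in 12 of 17 windows, with a median of −0.711 points but a mean of 2.54 points, at 6.93% ± 4.25 against 4.39% ± 0.453. The positive mean came from combination replicate 1 (9.93%), as replicate 2 stood at 3.93%, below both Vehicle libraries. Among them Mbd4, a methyl-CpG-binding glycosylase, had 3.24% ± 2.2 and 0% (up to 0.213%), and Dnmt3b, a de novo methyltransferase, 3.3% ± 0.983 and 0.236% ± 0.333. Fry gave the direction down with an adjusted p of 0.0469, which passed in 3 of 16 alternatives (range 0.00962 to 0.587), while camera gave an adjusted p of 0.631. Interferon genes were lower in 10 of 13 windows, with a median of −0.929 points and a mean of 2.95 points, at 10.5% ± 1.66 against 7.54% ± 0.676. The interferon receptor gene Ifnar1 had 2.81% ± 0.998 and 0.0222% ± 0.0314, and Irf5, an interferon regulatory factor, 4.04% ± 1.92 and 0.0423% ± 0.0598. Fry's mixed test of this list gave an adjusted p of 0.0399, which passed in 6 of 16 alternatives (range 1.75e-06 to 0.657), and camera an adjusted p of 0.631. Fry tests a list against no change and not against other windows, and windows without a methylated read were more frequent throughout the combination libraries than in Vehicle, as given above.

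Myeloid genes were lower in 6 of 10 windows, with a median of −1.22 points and a mean of 3.63 points, at 12.5% ± 2.83 against 8.91% ± 4.21. Cebpd, a transcription factor of the C/EBP family, had 4.11% ± 2.15 in Vehicle and 0.0274% ± 0.0388 in the combination. Gfi1, a repressor in granulocyte differentiation, had 0.848% ± 0.401 and 0% (up to 0.169%), and 3.36% ± 0.410 with AZA. Cell cycle genes stood near 0 in every group, at 1.43% ± 0.410 in Vehicle and 1.63% ± 0.941 in the combination, lower in 13 of 24 windows. Ccne1, the gene of cyclin E, had 2.97% ± 0.826 and 0% (up to 0.0429%), and Cdk1, the mitotic kinase, 2.23% ± 0.276 and 0% (up to 0.0727%). Tumour suppressor genes were lower in 12 of 22 windows, at 13.2% ± 1.54 against 12.7% ± 2.52. Dapk1, a kinase of cell death, had 2.27% ± 2.28 and 0% (up to 0.0625%), and Rbl1, a relative of the retinoblastoma gene, 0.507% ± 0.376 and 0% (up to 0.0334%). The MAPK genes were lower in 16 of 30 windows, at 6.09% ± 1.79 against 5.12% ± 0.970. Spry4, a feedback inhibitor of the pathway, had 2.44% ± 2.65 and 0% (up to 0.0985%), and the kinase gene Map2k1 2.31% ± 2.37 and 0% (up to 0.145%). Housekeeping genes were higher in 8 of 13 windows, at 7.02% ± 6.64 against 5.11% ± 0.222. Only combination replicate 1 (11.7%) carried the higher mean, and replicate 2 (2.33%) was below both Vehicle libraries. Eif4a2, a translation initiation factor, had 0.546% ± 0.772 and 9.998% ± 5.40, and the ribosomal protein gene Rpl13a 0.593% ± 0.729 and 13.5% ± 8.65.

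Germline genes kept high levels, 91.3% ± 4.29 in the combination against 93.1% ± 0.300 in Vehicle, and were lower in 10 of 14 windows with a median of −3.07 points. The lower mean came from combination replicate 2 (88.3%), as replicate 1 (94.3%) stood above both Vehicle libraries. Tuba3b, a tubulin gene of the testis, had 99.95% ± 0.00763 in Vehicle and 91.2% ± 6.20 in the combination (edgeR adjusted p = 0.938). Tdrd1, of the piRNA pathway, had 97.2% ± 3.95 and 90.6% ± 0.740. Imprinted genes stood at intermediate levels, 46.6% ± 2.30 against 45.2% ± 2.77, with a median of −2.37 points and a mean of 1.38 points. Inpp5f, which has imprinted transcripts, had 1.75% ± 2.48 in Vehicle and 62.9% ± 43.2 in the combination, and Plagl1, an imprinted zinc finger gene, 58.9% ± 2.16 and 82.6% ± 16.1. Developmental transcription factors were lower in 17 of 32 windows, with a median of −0.736 points and a mean of 1.58 points, at 15.3% ± 2.53 against 13.7% ± 0.907. Gata6 had 7.20% ± 6.34 and 0% (up to 0.752%), and the neurogenic factor gene Neurog2 8.71% ± 8.93 and 0% (up to 0.673%).

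Markers of other cell types stood in few windows. Lymphoid genes had 13.7% ± 6.30 in the combination against 11% ± 0.0739 in Vehicle over 4 windows, with Tcf7, a T cell transcription factor, at 21.5% ± 7.46 against 12% ± 0.492. The higher list mean lay in combination replicate 1 (18.2%), while replicate 2 (9.28%) was below both Vehicle libraries. Cd4, the T cell coreceptor, had 0% (up to 0.0631%) against 0.0364% ± 0.0515. Stromal and endothelial genes had 43.3% ± 19.8 against 47.9% ± 4.72 over 4 windows, with the endothelial gene Emcn at 100% against 97.6% ± 3.46 and the osteoblast factor gene Sp7 at 12.6% ± 16.8 against 29.9% ± 3.6. Their median (−5.50 points) was negative, while camera gave the direction up. Of the erythroid and megakaryocytic genes, only 2 had a window and no test was run: Itga2b, a platelet integrin, stood at 3.25% ± 0.653 against 0.627% ± 0.887 and the ankyrin gene Ank1 at 17.8% ± 2.66 against 17.1% ± 4.32. Among the genes fixed by name, Tet2, a dioxygenase of methylcytosine, had 0% (up to 0.255%) against 0.0193% ± 0.0274. Nras had 0% (up to 0.0348%) against 0.0880% ± 0.124, and Cdkn2b, a cell cycle inhibitor, 7.45% ± 8.30 against 0.965% ± 0.696. Idh1 and Dnmt3a had no window that passed the read minimum.

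**Figure D3:**
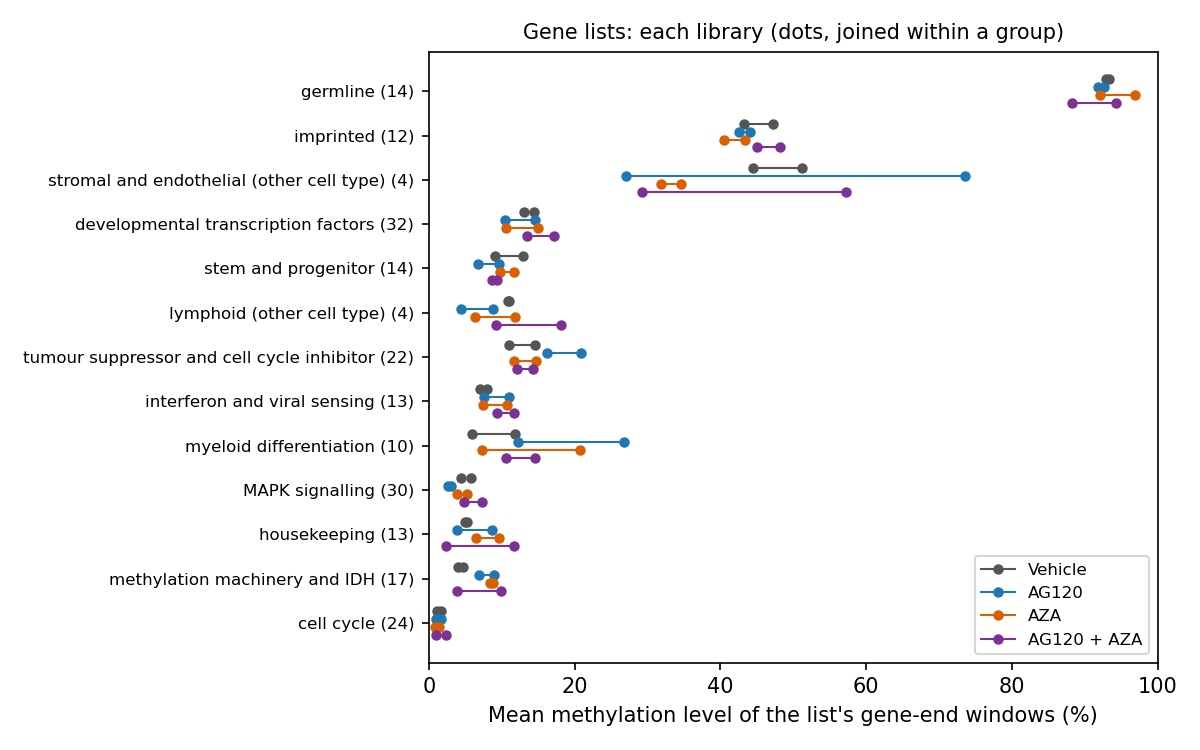
Mean methylation level of the gene-end windows of each tested list, in percent, with the number of measured genes in brackets; each dot is a library, joined within a group by a line. Germline genes lie near 93.1% and cell cycle genes near 1.43% in Vehicle, and for the stromal list the AG120 libraries lie far apart (SD 32.9).

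No list passed camera in the combination against Vehicle, with either correlation (lowest adjusted p = 0.323), and no member of any list passed when adjusted over the list alone. The edgeR quasi-likelihood test called 0 of 44190 tiles and 0 of 13003 windows, with 1746 tiles and 670 windows at an unadjusted p under 0.05. Limma called 0 of both (2495 tiles and 814 windows under 0.05). The likelihood ratio test called 96 tiles and 205 windows, 41 higher and 164 lower, and DESeq2 545 windows, 112 higher and 433 lower. Groups did not overlap in 37.9% of windows and 32.5% of tiles, where chance gives 33.3% without ties and less with them. Without overlap, 1522 windows were higher in the combination and 3405 lower, while by at least 10 points 745 were higher and 435 lower. All windows named here at 0% in the combination lie in libraries where 31.2 and 29.2% of windows had no methylated read.

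What AG120 added to AZA was read from the combination against AZA alone. B230354K17Rik (chromosome 17, 45432831 to 45434331), whose window overlaps that of the splicing factor gene Cdc5l, had 2.36% ± 0.471 with AZA and 0.00502% ± 0.00710 with the combination. Ppargc1a had 6.01% ± 3.22 and 0%, and Zc3h18, a zinc finger gene of nuclear RNA processing (chromosome 8, 122375564 to 122377064), 1.93% ± 0.282 and 0%, which allows up to 0.0238%. The edgeR p was 0.000476, 0.000528 and 0.000582, each with an adjusted p of 1. Interferon genes were lower in 9 of 13 windows, with a median of −1.27 points and a mean of 1.41 points (camera p = 0.0354, adjusted p = 0.460; adjusted p = 0.996 with an estimated correlation). Fry's mixed test gave an adjusted p of 0.0336 for the interferon list, past the threshold in 5 of 16 alternatives (range 0.00406 to 0.419), and of 0.00272 for the stem and progenitor list, past it in 12 of 16 (range 0.00273 to 0.568). The stem and progenitor windows were 6 higher and 8 lower, and camera gave an adjusted p of 0.773 (adjusted p = 0.996 with an estimated correlation). These fry tests too are against no change, and windows without a methylated read were more frequent with the combination than with AZA. Germline genes were lower in 10 of 14 windows, at 91.3% ± 4.29 against 94.5% ± 3.36, and stromal genes higher in 3 of 4, at 43.3% ± 19.8 against 33.3% ± 1.92. Among the other lists, imprinted genes stood higher in 6 of 12 windows and developmental transcription factors in 17 of 32.

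For the combination against AZA, no list passed camera and no member passed when adjusted over the list alone. The edgeR quasi-likelihood test called 0 of 44190 tiles and 0 of 13003 windows, with 1705 tiles and 625 windows at an unadjusted p under 0.05. Limma called 0 of both (2934 tiles and 908 windows under 0.05), the likelihood ratio test 321 tiles and 130 windows (31 higher, 99 lower), and DESeq2 550 windows (157 higher, 393 lower; 253 had no adjusted p). Groups did not overlap in 31.0% of tiles (33.3% by chance without ties). Of these, 6549 were higher and 7129 lower, while by at least 10 points 4285 were higher and 3175 lower. The mean tile difference was 1.24 points, between 0.556 without AZA replicate 2 and 1.93 without AZA replicate 1.

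What AZA added to AG120 was read from the combination against AG120 alone. B230354K17Rik had 3.34% ± 1.19 with AG120 and 0.00502% ± 0.00710 with the combination, and the overlapping window of Cdc5l (45433207 to 45434707) had 4.86% ± 1.64 and 0.00508% ± 0.00719. In Vehicle, Cdc5l stood at 1.09% ± 0.226 and B230354K17Rik at 1.44% ± 0.569. 1110059E24Rik had 2.72% ± 1.58 with AG120 and 0.00471% ± 0.00667 with the combination. The edgeR p was 0.000345, 0.000442 and 0.000592, each with an adjusted p of 1. Tumour suppressor genes were lower in 13 of 22 windows, at 13.2% ± 1.54 against 18.6% ± 3.25 (camera adjusted p = 0.628). Myeloid genes were lower in 8 of 10 windows, at 12.5% ± 2.83 against 19.5% ± 10.3, and developmental transcription factors higher in 20 of 32, at 15.3% ± 2.53 against 12.5% ± 2.87 (camera adjusted p = 0.628 for both). MAPK genes were higher in 17 of 30 windows, at 6.09% ± 1.79 against 2.82% ± 0.247 (camera adjusted p = 0.628).

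For the combination against AG120, no list passed camera and no member passed when adjusted over the list alone. The edgeR quasi-likelihood test called 0 of 44190 tiles and 0 of 13003 windows, with 1502 tiles and 589 windows at an unadjusted p under 0.05. Limma called 0 of both (2651 tiles and 817 windows under 0.05), the likelihood ratio test 294 tiles and 163 windows (60 higher, 103 lower), and DESeq2 532 windows (194 higher, 338 lower). Groups did not overlap in 27.8% of tiles (33.3% by chance without ties, and less with them). The mean tile difference was −0.308 points, and it was 0.788 without AG120 replicate 2 and −1.47 without AG120 replicate 1.

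The effect of each drug was also compared in the presence and absence of the other. Across 44190 tiles, the AZA effect without AG120 (AZA against Vehicle) and with it (combination against AG120) had a Pearson r of −0.0107 (interval −0.0200 to −0.00140) and a Spearman rho of −0.0121, and 49.8% of tiles had the same sign. Without AG120 replicate 2 this r was 0.00487. The AG120 effect without AZA and with it had r = 0.0212 (0.0119 to 0.0305) and rho = 0.00855, with the same sign in 50.6% of tiles. No library entered both sides of either comparison, and tiles are not independent replicates, so the intervals are too narrow. The mean r of tile levels between libraries was 0.881 within groups and 0.879 between groups. With a spread this wide, an r near 0 does not show that an effect differed with the other drug. The edgeR quasi-likelihood test called 0 of 44190 tiles for the interaction, the average AZA effect and the average AG120 effect, with 1194, 1172 and 1502 tiles at an unadjusted p under 0.05. Limma called 0 tiles for each (2354, 2261 and 2510 under 0.05), and the likelihood ratio test 186, 218 and 410 tiles.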

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

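The tests of shifted reads, of a rise at the measured positions, of covered positions, of read number and of few molecules were chosen only after the result was seen; the test of strand deviations and both counts of splits were not. Of 138 pairs of drug effects, with and without the other drug, 12 went opposite ways in every library. Chance gives 7.67 (5.56%) if no levels tie. All 12 were among 88 pairs of named windows (4.89 by chance without ties), which had been named for small p-values. The differences were not tested by this comparison. Aven, an inhibitor of apoptosis, was lower with either drug alone than in Vehicle and higher in the combination than with either drug, so that each drug's effect differed by 5.77 points. B230354K17Rik and Cdc5l, a splicing factor gene with an overlapping window, went the other way, with differences of −4.26 and −6.38 points for both drugs. The deubiquitinase gene Josd1 was lower with each drug alone and slightly above 0 in the combination, a difference of 1.72 points for both drugs. Cc2d1b and Gm12743, which share their reads, differed by 3.07 points in the AZA effect. Gfi1, a myeloid repressor, differed by −2.72 points in the AZA effect, being higher with AZA than in Vehicle and lower in the combination than with AG120. The ribosomal protein gene Rpl13a differed by 13.2 points in the AZA effect, with 13.5% ± 8.65 in the combination. The edgeR quasi-likelihood test of the interaction called 0 of 13003 windows, with 351 at an unadjusted p under 0.05, limma 0, the likelihood ratio test 60 and DESeq2 256.

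On Y, outside the chromosomes compared, CpG calls in ppm of a library's calls exceeded both Vehicle libraries (1861 and 1658) in AG120 replicates 1 (2312, 95% Wilson interval 2303 to 2322) and 2 (2541, 2532 to 2550), AZA replicate 1 (1972, 1965 to 1980) and combination replicates 1 (2437, 2427 to 2447) and 2 (2382, 2372 to 2393). Between 97.4 and 99.0% of these calls lay beyond 90 Mb of Y in each library.

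Counted by reads, mean methylation was 50.6% ± 3.08 in the 4 libraries with AG120 and 42.7% ± 2.22 in the 4 without, a difference of 7.83 points. A mean rise of this size over the shared positions, each counted once, is excluded. The interval of that difference ended at 2.67 points, and at most at 3.59 with a library left out. A rise confined to the most deeply read positions is not excluded, because they weigh little when each position counts once. Reads shifted between positions may account for a part of the difference, of a size not measured. It was 0.651 points with each shared position counted once, and positions over 80% took 6.52 points more of the calls with AG120. Fewer covered positions cannot be told apart from the drug. This was read from the methylated share of all calls of a library, not from the level at the shared positions. That share followed covered positions over the 8 libraries (r = −0.814, exact p = 0.0217; rho = −0.857, exact p = 0.0107). It did so less closely by r without the 2 farthest (r = −0.637, exact p = 0.172; rho = −0.886, exact p = 0.0333). Its r was −0.0730 within the 4 libraries with AG120 and −0.751 within the 4 without, too few to test. A biological difference in cells treated with AG120 stays open, as untested.

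At 2636 intermediate positions, 22.5 to 37.6% stood at exactly 0 or 100% in a library. Too few reads are excluded, since counting independent reads leaves an excess of at least 22.5 points in each of the 8 libraries. Stable differences between mice are excluded as the main cause only at 373 CpGs measured on both strands. There, deviations of the strands from their means had r = 0.0942 (0.0325 to 0.158). A smaller part is not excluded, and positions without a measured partner strand were not tested. Reads copied from few molecules may be the cause, as the share followed the number of covered positions (r = −0.984, exact p = 0.000198; rho = −0.952, exact p = 0.00114), also without the 2 farthest libraries (r = −0.948, exact p = 0.00556) and within the 4 libraries with AG120 (−0.994) and the 4 without (−0.800), too few to test. A biological difference between the treatments stays open, as untested, because the groups differ in covered positions.

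The likelihood ratio test on windows, with the libraries in 2 groups of 4, called 56 windows for the AZA split and 136 for the AG120 split. For AZA, 7 of the 35 splits gave as many and the highest of the others, the AG120 split itself, gave 136, so chance cannot be excluded, and a test too permissive for this spread could account for the calls. For AG120, 1 of the 35 splits, the real one, gave as many and the highest of the others 115. That is the smallest share that 35 splits can give (0.0286), under 0.05 for this count alone. It is unadjusted for the other drug, so chance is not firmly excluded. The AG120 split also parts the 4 libraries with the fewest covered positions from the other 4, so the difference in coverage stays open. An effect of AG120 stays open too, as untested apart from it.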

How the results depend on the processing

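The whole gene and the gene end with fewer covered positions were alternatives chosen only after the data were seen; the others were planned. The count of 0 tiles and 0 windows from the edgeR quasi-likelihood test held under other read minimums, tile sizes, windows, library sizes, autosomes alone, limma with and without centring, a minimum difference of 10 points, and leaving out each library, where the lone library of a group was assumed to vary like the others. The likelihood ratio test moved the tile counts to 8, 8, 96, 321 and 294 for AG120, AZA and the combination against Vehicle and the combination against AZA and AG120, and to 186, 218 and 410 for the interaction, the average AZA and the average AG120 effect. It moved the window counts to 2, 205, 130 and 163 for AZA and the combination against Vehicle and the combination against AZA and AG120. DESeq2 moved them to 197, 92, 545, 550 and 532 in the order of the first 5 tile counts; on simulated data both tests made calls on windows that were not changed, 13 to 123 and 117 to 298 over the 5 comparisons. Counting every read turned the AZA difference in mean methylation to 1.74 points and brought the AG120 difference of 7.83 points past the threshold. With each library left out in turn, r ranged from −0.0249 to 0.00487 for the AZA effect, positive without AG120 replicate 2, and from 0.00151 to 0.0301 for the AG120 effect. Fry's direction for the methylation machinery list in the combination against Vehicle reversed over the whole gene (adjusted p = 0.483). The cause of these moves was not tested. A replicate block called 0 tiles and 0 windows, and the replicate numbers showed no pairing of libraries across groups (6 correlations, −0.00429 to 0.0228). A pairing hidden by the spread between libraries is not excluded by these correlations. Of the summary values 523 kept their count, side of the threshold or place within an interval. Another 21 moved in count or out of the interval, 2 changed sign and 1 newly passed the threshold. Of the values for named genes and lists 934 kept their side of the threshold, 40 moved past it, 44 no longer passed it and 1 changed direction. The 47 pairs of a named gene (44 genes) and a comparison passed the threshold only under the likelihood ratio test (13) or DESeq2 (27); their sign changed in 30 of 939 results, 19 of them over the whole gene. Coverage is a limit too, as only 3.45% of covered positions had a read in all libraries.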

Other observations

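The chromosome comparison, the share of CpGs with unlike strands and the splits by limma were tests chosen only after the result was seen. Tiles on X had a mean level of 65.7% ± 1.89 in Vehicle, 68.6% ± 3.34 in AG120, 64.6% ± 0.637 in AZA and 69.1% ± 0.524 in the combination, above every autosome in each group. Chromosome 12 was the highest of the autosomes in Vehicle, at 52.3% ± 0.515, and chromosome 11 the lowest, at 42.2% ± 0.866. Mean levels with AZA were below Vehicle on all 20 chromosomes, by −1.83 points on chromosome 8 to −0.654 points on chromosome 11. The combination was above AZA on all 20, by 0.680 points on chromosome 12 to 4.50 points on X. AG120 was above Vehicle on 18 and below on 2 (−0.276 points on chromosome 5 to 2.88 points on X), and the combination was above Vehicle on 6 and below on 14 (−0.397 points on chromosome 7 to 3.41 points on X). Chromosomes of a library are not independent replicates, so these counts carry no test.

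Azacitidine blocks maintenance methylation at replication, so a candidate explanation for CpGs with unlike strands was methylation left on 1 strand by AZA. At 917 CpGs measured on both strands in all 8 libraries, strands differed by more than 50 points in 8.34% ± 2.26 with AZA and 6.32% ± 2.63 without, a difference of 2.02 points (exact permutation p = 0.343, two-sided). The spread between libraries keeps this open. With AG120 the share was 8.75% ± 1.95 against 5.92% ± 2.36 without (exact permutation p = 0.0857). Over all CpGs measured on both strands in each library, which differ between libraries, it was 12.1% ± 0.851 with AG120 and 9.36% ± 1.136 without (exact permutation p = 0.0286). It was 11.5% ± 1.47 with AZA and 9.95% ± 1.81 without (exact permutation p = 0.257). With AG120 there were 94025 to 170637 such CpGs, at mean levels of 28.3 to 40.8%. Without it there were 195566 to 296284, at 20.7 to 25.6%. An effect of AG120 therefore cannot be told apart from which CpGs were read.

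By limma with the libraries in 2 groups of 4, the AZA split and the AG120 split each called 0 tiles, the highest of the other splits called 0, and so all 35 of 35 splits gave as many for each drug. With 0 in every split, these counts say nothing about chance. At an unadjusted p under 0.05 the AZA split had 2165 tiles, against 2481 in the highest other split, which was the AG120 split, and the highest of the splits other than AG120's had 2381.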
